A study of Homo sapiens with 48 samples.

How the data were processed

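Ishikawa cells, an established line from a human endometrial adenocarcinoma, were treated with estradiol (E2, 10 nM), with 4-hydroxytamoxifen (OHT, 1000 nM, the active metabolite of tamoxifen) or with the ethanol vehicle for 24 or 48 h. The RNA of treated and vehicle cells was labelled with Cy3 and Cy5 in both orientations and hybridised together to spotted oligonucleotide arrays. The gene collection was spread over 2 array sets, each with 24 arrays, so 48 samples fell into 8 groups of 6 arrays, 3 with the treated RNA in Cy5 and 3 with it in Cy3. The general description of the study says that the cells were serum-starved for 72 h before treatment, while the sample descriptions say that they were grown for 72 h in medium with charcoal-stripped serum. The labels do not state which of these holds.

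The deposited values are log2 ratios of the 2 channels of each spot, made by the authors with GenePix Pro 3.0 according to the study description. How background, spot quality and normalization were handled is not stated, and the array medians differed from 0 and from each other, so the values were read as not normalised. A value of 16.61 marked spots without a usable ratio and was read as missing. No label states which channel is the numerator. Spots that carry signal in a single dye lay below -3 in both orientations, 228 on set 1 and 106 on set 2, so 1 dye was over the other on every array and the ratio was not treated over vehicle. On set 2 all 106 of these spots, and on set 1 160 of 228, sat in the corners of the printing blocks. The ratio was taken as Cy5 over Cy3, and values of arrays with treated RNA in Cy3 were multiplied by -1. If the files held Cy3 over Cy5, each direction given for a drug would be the opposite.

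Spots were named by the gene symbol of the array annotation. Of 21120 spots per array, 11974 on set 1 and 18570 on set 2 had 1 symbol, which gave 4930 and 8298 genes. Spots with several symbols, 56 and 22, were left out, and spots not listed, 9090 and 2528, were tested apart. Spots were averaged to oligonucleotides and these to genes, and each array was centred on its median. Genes with a value on at least 4 of the 6 arrays in every group of a set were tested, 787 on set 1 and 3340 on set 2. This filter was set by missing values, since spot intensities were not used here. Of the spot values, 73.7% were missing on set 1 and 33% on set 2. With ratios alone, the number of arrays and of spots with a value limit the precision.

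Each set was fitted with limma 3.58.1 in R 4.3.3, with 4 coefficients for drug and time and 1 dye coefficient per gene, followed by empirical Bayes moderation. Each drug was tested against vehicle at 24 and 48 h, E2 against OHT at each time, and 48 h against 24 h for each drug, which makes 8 comparisons per set. All tests were two-sided. P values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called changed at an adjusted p under 0.05. The labels do not say which forward and reverse arrays carry the same RNA, so each array entered as 1 sample. The p values measure the spread between arrays, which may hold technical repeats of 1 RNA, and not the spread between independent cultures. Errors are standard errors (SE) of the fit and intervals are 95% confidence intervals.

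Before the data were examined, 22 gene lists were fixed: estrogen receptor targets, endometrial hormone genes, cell cycle and proliferation, cholesterol synthesis, fatty acid synthesis, unfolded protein response, heat shock proteins, growth factors and the IGF system, immediate early genes, nuclear receptors and coregulators, BCL2 family and caspases, interferon response, xenobiotic and oxidative defence, extracellular matrix and adhesion, WNT signalling, epithelial keratins, housekeeping genes, ribosomal proteins, oxidative phosphorylation, proteasome, and markers of 2 groups of other cells, stromal cells and blood or endothelial cells. Lists with 5 or more measured genes were tested by limma's camera with a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and by fry. On set 1, 2 lists could be tested.

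The named genes followed a rule set before the data were examined. For each drug against vehicle these were up to 8 risen and 8 fallen genes with the largest change among those called with the same sign on at least 5 of the 6 arrays. Where a direction had none, the 3 genes with the smallest p were taken. For the other comparisons up to 5 per direction were allowed. Up to 4 members of each list with the smallest p, and ESR1, PGR, GREB1, TFF1, ALPP, MYC and MKI67 where measured, were added. Other genes of this rule are not reported here. Genes named outside the rule are said to be so.

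The pipeline was tested on simulated data with the arrays and missing values of 5 comparisons per set and 200 changed genes. At a log2 change of 1, from 42% to 90% of the changed genes were called, and at a log2 change of 2, from 90% to 100%, while 2.41% to 6.21% of the called genes were unchanged ones. The simulated noise was independent between arrays.

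The alternatives fixed before the data were examined were no centring, arrays scaled to the same spread (limma's normalizeMedianAbsValues), no filter on missing values, genes measured on all arrays alone, no dye coefficient, the compared arrays alone, array weights, oligonucleotides tested apart, forward and reverse arrays averaged in pairs over the 6 possible matchings, and leaving out each array of the compared groups in turn. Added after the data were seen were a dye coefficient for each class of arrays with a similar number of measured spots, a fit without the sparse arrays (those with under 3000 spots with a value on set 1 or under 10000 on set 2), the removal by loess of each array's trend on spot brightness, and, for E2 against OHT, a fit on the differences within pairs of arrays of 1 time and orientation with neighbouring slide numbers, for genes with at least 4 such differences. The stand-in for brightness was the share of a gene's spots that had a value on the sparse arrays.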

Results

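Relative RNA levels were measured in Ishikawa cells after E2 or OHT, each against vehicle on the same array, on 2 array sets that hold different parts of the gene collection. Each group of drug, time and set had 6 arrays. The number of spots with a value ran from 1158 to 8566 of 21120 on set 1 and from 3605 to 20295 on set 2. On set 1 the group medians were 7273.5 spots for E2 at 24 h, 4457.5 for E2 at 48 h, 7534.5 for OHT at 24 h and 4184 for OHT at 48 h. On set 2 they were 16642.5, 12152.5, 15842.5 and 12451.5 in the same order. The sparse arrays were 2 of E2 at 48 h and 2 of OHT at 48 h on set 1. On set 2 they were 1 of E2 at 24 h, 3 of E2 at 48 h and 3 of OHT at 48 h. The median SE of a log2 ratio to vehicle was between 0.217 and 0.254 in all 8 groups. The fit takes 1 variance per gene over all arrays of a set, so these errors could differ only through missing values. Their likeness does not show that the groups were equally precise. ESR1, MYC and MKI67 had no spot listed under those symbols and were not analysed here. TFF1, an estrogen-induced secreted peptide, had values on 3, 1, 3 and 0 arrays of E2 at 24 h, E2 at 48 h, OHT at 24 h and OHT at 48 h, too few to test.

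**Figure D1:**
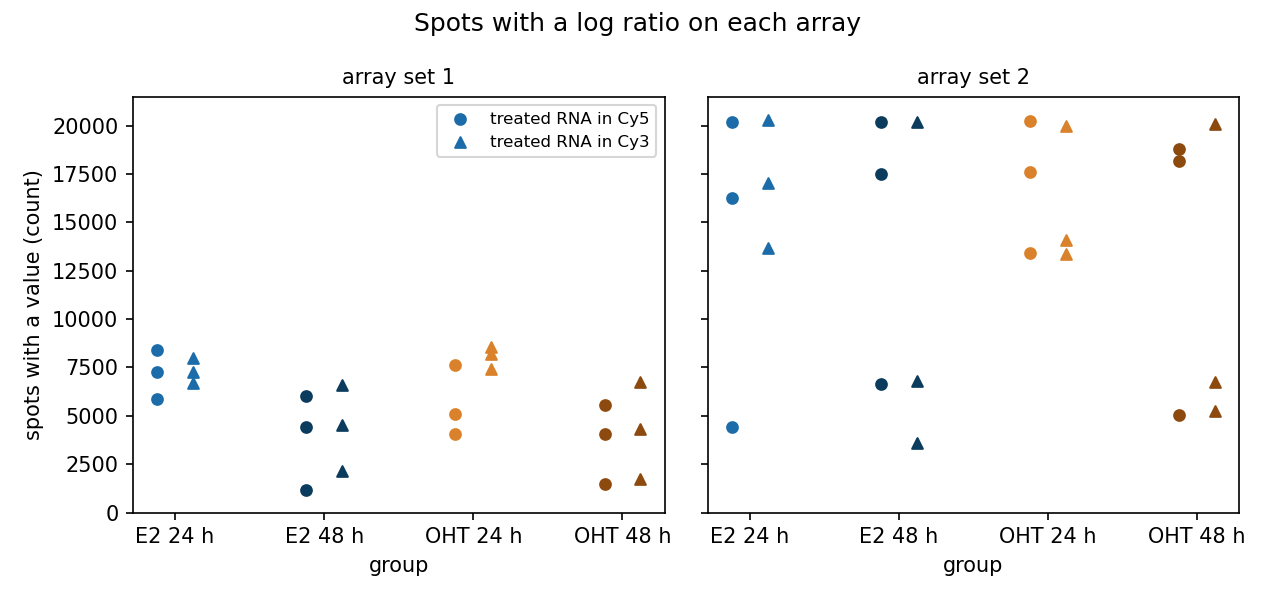
Number of spots with a value on each array (vertical axis) by drug, time and array set, with circles for treated RNA in Cy5 and triangles for treated RNA in Cy3. Set 2 arrays ran from 3605 to 20295 spots and set 1 arrays from 1158 to 8566.

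E2 at 24 h was compared with vehicle to find the earlier response to the estrogen. On set 2, KCNJ5, an inwardly rectifying potassium channel subunit, rose by a log2 ratio of 1.24 (SE 0.20, n = 5, higher on 5 of 5 arrays, adjusted p = 0.00283). PECR, a peroxisomal enoyl-CoA reductase, rose by 1.19 (SE 0.17, n = 6, 6 of 6 arrays, adjusted p = 0.000952), and ESPN, which bundles actin filaments, by 1.17 (SE 0.18, n = 6, 6 of 6 arrays, adjusted p = 0.001). SLC7A5, a transporter of large neutral amino acids, rose by 1.07 (SE 0.19, 5 of 6 arrays, adjusted p = 0.00851), CKB, the brain-type creatine kinase, by 0.85 (SE 0.18, 6 of 6 arrays, adjusted p = 0.0266) and KAZN, a protein of cell junctions, by 0.70 (SE 0.15, 5 of 6 arrays, adjusted p = 0.043). On set 1, GDPD5, a glycerophosphodiester phosphodiesterase, rose by 1.71 (SE 0.29, n = 5, 5 of 5 arrays, adjusted p = 0.00572) and CABLES1, which binds cyclin-dependent kinases, by 1.28 (SE 0.20, n = 6, 6 of 6 arrays, adjusted p = 0.00324). SELENOT, a selenoprotein of the endoplasmic reticulum, fell by 1.29 (SE 0.26, 6 of 6 arrays, adjusted p = 0.0266), with 1 array at -3.35 and the others between -1.31 and -0.42. NEDD8, a ubiquitin-like protein modifier, fell by 1.05 (SE 0.21, 5 of 5 arrays, adjusted p = 0.0266). The calls of KAZN, CKB and SELENOT were lost in 8 of 12, 7 of 12 and 6 of 11 alternatives, and that of CABLES1 in 1 of 10.

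GREB1, an estrogen receptor target, stood at 0.78 under E2 at 24 h (interval 0.40 to 1.16, 5 of 5 arrays, adjusted p = 0.0999), so it did not pass. Its 2 oligonucleotides gave 1.05 (unadjusted p = 1.78e-05) and 0.49 (unadjusted p = 0.0299). Values of single oligonucleotides, here and below, are from a limma fit without the filter on missing values. With oligonucleotides tested apart under the filter, GREB1 was not called at 24 or 48 h of E2. PGR, the progesterone receptor, stood at 0.22 (interval -0.52 to 0.95) and ALPP, placental alkaline phosphatase, at -0.29 (interval -0.72 to 0.14). None of the 10 measured estrogen receptor targets passed over all genes tested. Adjusted over the list alone, GREB1 rose and XBP1, a transcription factor of the unfolded protein response, fell (log2 ratio -0.66). The list had a median of 0.05, a mean of -0.01 and an upward camera test that did not pass (adjusted p = 0.777). The 47 genes of oxidative phosphorylation, the subunits of the respiratory chain and ATP synthase, lay lower than other genes on set 2 by camera (median -0.19, adjusted p = 0.0117, 0 passing over all genes and 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.859, and the median was -0.34 without centring and -0.13 with the brightness trend removed. The 6 genes of this list on set 1 also lay lower (median -0.42, adjusted p = 0.0383), with an adjusted p of 0.395 with an estimated correlation and no call in 7 alternatives (adjusted p from 0.0533 to 0.398, median -0.26 without the filter), and adjusted over the list alone 3 fell and 1, NDUFA11, rose. On set 1 NDUFB10 stood at -0.74 and ELP4, a subunit of the Elongator complex, at -1.04 (adjusted p = 0.216 for each), and FSTL1, a secreted glycoprotein, at -0.76 (adjusted p = 0.229).

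In total 8 of 3340 genes changed on set 2 and 2 of 787 on set 1 under E2 at 24 h, and 316 and 76 had an unadjusted p under 0.05. The 8 were 6 higher and 2 lower, while the 316 were 77 higher and 239 lower, and the 76 of set 1 were 44 higher and 32 lower. The set 2 count was 0 without centring, 0 with the compared arrays alone, 43 (18 higher and 25 lower) with arrays scaled to the same spread, 15 without the sparse arrays and 457 (167 higher and 290 lower) with array weights. It was 5 without replicate 1, 3 without replicate 3 and 5 without replicate 6. Replicate 2 of this group on set 2 had a wider spread of log2 ratios. Its median absolute deviation was 1.05, against 0.423 to 0.747 on the others. On set 1 the count was 16 with array weights, 4 with the trend removed, 0 with a dye coefficient per class, 1 without replicate 1 and 1 without replicate 3.

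**Figure D2:**
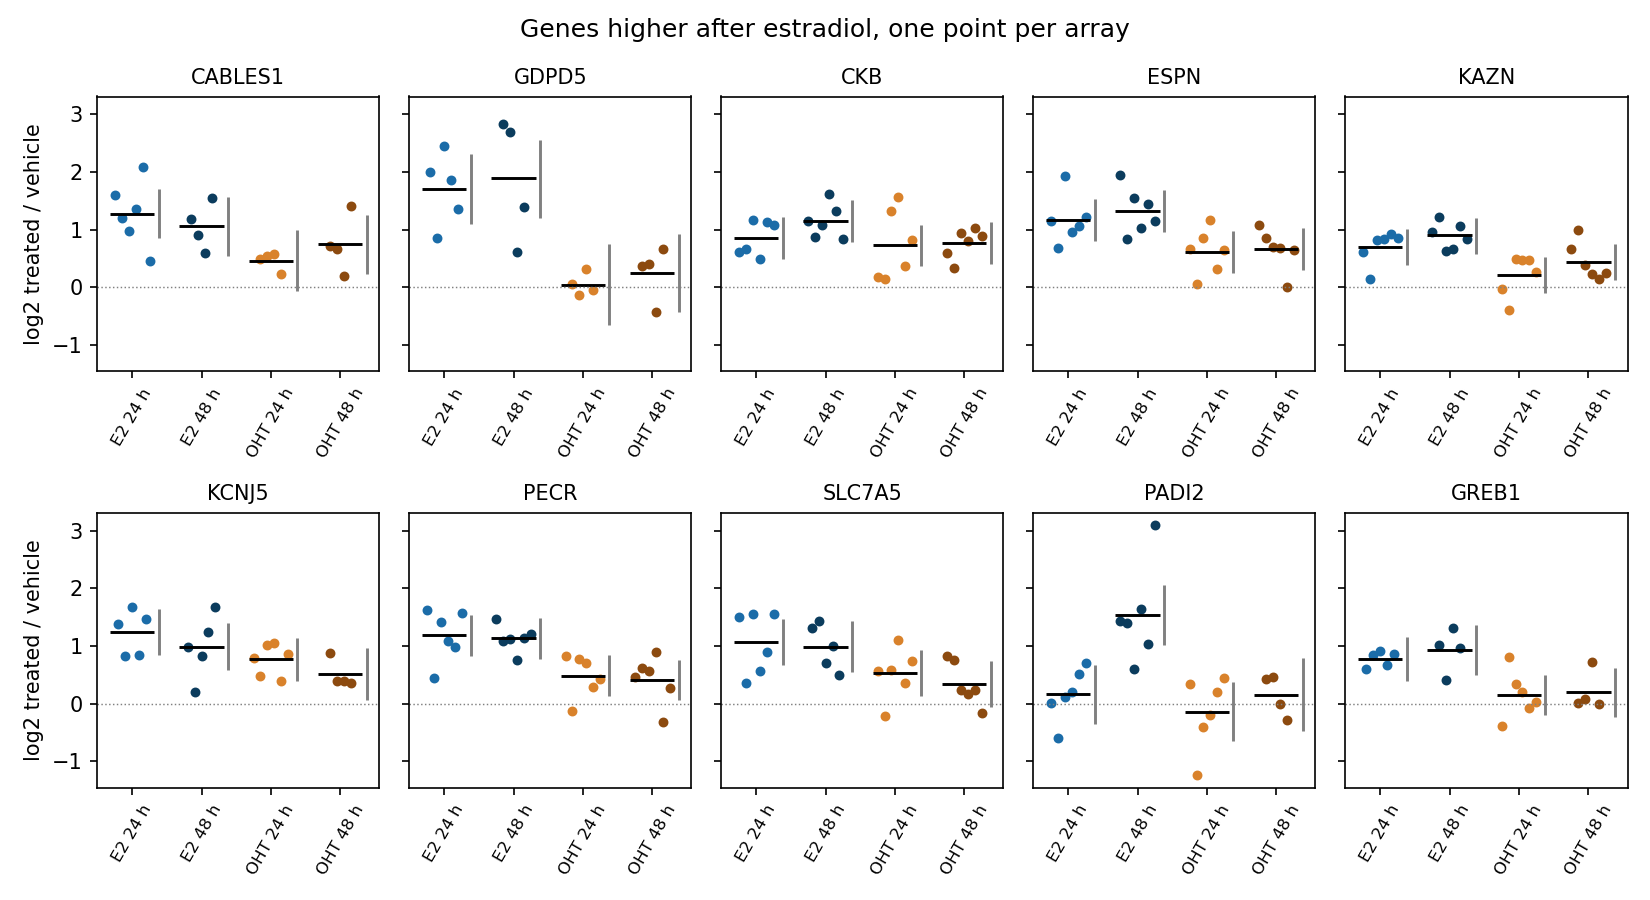
Log2 ratio of treated to vehicle (vertical axis) on each array, after removal of the dye effect, for CABLES1, GDPD5, CKB, ESPN, KAZN, KCNJ5, PECR, SLC7A5, PADI2 and GREB1 in the 4 groups of drug and time. Black lines are fitted means and grey bars 95% confidence intervals; ESPN stood at 1.17 and 1.33 under E2 and at 0.62 and 0.66 under OHT at 24 and 48 h.

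E2 at 48 h was compared with vehicle to find the later response. The 6 genes that rose at 24 h on set 2 were among the 8 that rose at 48 h. ESPN rose by 1.33 (SE 0.18, n = 6, 6 of 6 arrays, adjusted p = 0.000228), CKB by 1.15 (SE 0.18, 6 of 6 arrays) and PECR by 1.13 (SE 0.17, 6 of 6 arrays), both with an adjusted p of 0.000824. KAZN rose by 0.90 (SE 0.15, 6 of 6 arrays, adjusted p = 0.00232), SLC7A5 by 0.99 (SE 0.21, 5 of 5 arrays, adjusted p = 0.0406) and KCNJ5 by 0.98 (SE 0.20, 4 of 5 arrays, adjusted p = 0.0295), the last outside the naming rule and chosen after its values were seen. PADI2, which converts arginine to citrulline in proteins, rose by 1.54 (SE 0.25, n = 6, 6 of 6 arrays, adjusted p = 0.00214). MMP17, a membrane-anchored matrix metalloproteinase, rose by 3.48 with a wide error (SE 0.69, interval 2.04 to 4.92, n = 5, 5 of 5 arrays, adjusted p = 0.0295). On set 1, GDPD5 rose by 1.89 (SE 0.32, adjusted p = 0.0122) on its 4 measured arrays, which is below the 5 arrays of the naming rule and was chosen after its values were seen. NDUFA11, a complex I subunit, rose by 0.88 (SE 0.19, n = 6, 6 of 6 arrays, adjusted p = 0.0379). The calls of SLC7A5, NDUFA11 and MMP17 were lost in 8 of 11, 7 of 12 and 6 of 11 alternatives, and those of ESPN and PECR in 1 of 12 each.

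GREB1 stood at 0.93 (interval 0.49 to 1.36, 4 of 4 arrays, adjusted p = 0.0555), with 1.35 (unadjusted p = 4.3e-06) and 0.38 (unadjusted p = 0.172) for its 2 oligonucleotides, and was the 1 estrogen receptor target that rose when adjusted over the list alone (camera adjusted p = 0.853 for the list, median 0.11). PGR stood at 0.31 (interval -0.54 to 1.15), with 1 array at -1.64 and the others between 0.80 and 1.13 (0.88 with an adjusted p of 0.0433 without the sparse arrays), and ALPP at -0.18 (interval -0.61 to 0.24). VRK1, a chromatin kinase, stood at -0.72, the histone gene H2AC18 at -0.63 (adjusted p = 0.0529 for each) and IGFBP7, an IGF-binding protein, at -0.86 (adjusted p = 0.0627). On set 1 TP53INP2 stood at -1.27 (adjusted p = 0.0951), and AJUBA and FSTL1 at -0.78 and -0.86 (adjusted p = 0.146 for each). The oxidative phosphorylation genes of set 2 lay lower by camera (47 genes, median -0.21, adjusted p = 0.001, 0 passing singly and 0 adjusted over the list alone), with an adjusted p of 0.88 with an estimated correlation and a median of -0.03 without centring. The 16 proteasome genes also lay lower (median -0.18, adjusted p = 0.0147, 0 passing singly and 0 adjusted over the list alone), again with an adjusted p of 0.88 with an estimated correlation. The proteasome list no longer passed with a dye coefficient per class of arrays (adjusted p = 0.063), without centring (median -0.01, adjusted p = 0.125) or with genes measured on all arrays alone (adjusted p = 0.198).

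In total 8 of 3340 genes changed on set 2 and 2 of 787 on set 1 under E2 at 48 h, and 270 and 70 had an unadjusted p under 0.05. Without the sparse arrays 7 genes passed on set 2, of which 2 were among the 8, ESPN and PECR, and the set 2 count was 1 with the compared arrays alone, from 4 to 39 over the matchings of averaged pairs, 18 with the trend removed, 19 with array weights, 22 with a dye coefficient per class and 5 without replicate 1. The set 1 count was 18 with array weights, 8 without the filter, 5 with the trend removed, 0 with scaled arrays, 0 with the compared arrays alone, 0 without replicate 1, 0 without replicate 2 and 1 without replicates 4, 5 or 6.

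OHT at 24 h was compared with vehicle to find the earlier response to the antiestrogen, which acts as a partial estrogen in endometrial cells. Here 51 genes fell and 5 rose on set 2. Replicate 2 of this group had a wider spread of log2 ratios, with a median absolute deviation of 1.25 against 0.35 to 0.559 on the others. The neighbouring slide, replicate 2 of E2 at 24 h, was also wide, at 1.05. PRDX1, a peroxide-reducing enzyme, fell by 1.46 (SE 0.34, n = 6, lower on 6 of 6 arrays, adjusted p = 0.0366), and from 0.973 to 1.52 over the alternatives. NDUFA13, a complex I subunit, fell by 1.17 (SE 0.26, 6 of 6 arrays, adjusted p = 0.0309). Of the 39 ribosomal protein genes, 7 fell, or 10 adjusted over the list alone, among them RPS4X by 1.35 (SE 0.30), RPL6 by 1.34 (SE 0.30), RPL35 by 1.27 (SE 0.28) and RPS26 by 1.14 (SE 0.25), each on 6 of 6 arrays and with an adjusted p of 0.0309. RPL19 fell by 1.20 (SE 0.28, adjusted p = 0.0366), as did RPL19P9, a pseudogene of RPL19 whose sequence resembles it. One RPS4X array lay at -3.12 and the others between -1.47 and -0.68.

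Of the 16 proteasome genes, 2 fell, or 8 adjusted over the list alone, namely the core subunits PSMB6 by 1.10 (SE 0.20, adjusted p = 0.0238) and PSMA6 by 0.91 (SE 0.20, adjusted p = 0.0309). Of the 12 genes of the unfolded protein response, 1 fell, or 4 adjusted over the list alone. This was HSPA5, the main chaperone of the endoplasmic reticulum, which fell by 0.96 (SE 0.23, adjusted p = 0.0366). ASNS, asparagine synthetase, stood at -0.83 (adjusted p = 0.0517), and the chaperones HSP90B1 and CANX at -0.98 and -0.71 (adjusted p = 0.053 for each). All 3 lists lay lower than other genes by camera with an adjusted p of 0.00201 each, and medians of -0.39 for ribosomal proteins, -0.47 for the proteasome and -0.38 for the unfolded protein response. With an estimated correlation the adjusted p was 0.689, 0.223 and 0.488 in that order. Removal of the brightness trend ended the call of the ribosomal list (median -0.16, adjusted p = 0.0647) and left those of the proteasome at a median of -0.25 and of the unfolded protein response at -0.32 (adjusted p = 0.0127 for each). Without the filter the medians were -0.15 for ribosomal proteins, -0.15 for the proteasome and -0.22 for the unfolded protein response, over 60, 29 and 19 genes, and with genes measured on all arrays alone none of the 3 lists passed (adjusted p = 0.216, 0.238 and 0.154). Their medians over the 30, 9 and 8 genes left were -0.40, -0.41 and -0.48. The median of all genes was -0.18 there, against -0.06 in the main fit. Fry, which does not compare a list with other genes, called 3 of the 8 lists it could test on these genes. Of the oxidative phosphorylation genes 2 of 47 fell, NDUFA13 and ATP5MC1, a subunit of ATP synthase, and the list did not pass (adjusted p = 0.0859).

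PIGR, the receptor that carries polymeric immunoglobulins across epithelia, rose by 0.82 (SE 0.18, n = 6, 6 of 6 arrays, adjusted p = 0.0309). KCNJ5 rose by 0.77 and CKB by 0.73, both also raised by E2, and ICA1, an islet autoantigen, by 0.71 (adjusted p = 0.0366 for each). NDST1, an enzyme of heparan sulfate synthesis, rose by 0.71 (adjusted p = 0.0402). GREB1 stood at 0.15 (interval -0.20 to 0.50), with 0.32 (unadjusted p = 0.06) and -0.03 for its 2 oligonucleotides, PGR at -0.06 (interval -0.80 to 0.68) and ALPP at -0.24 (interval -0.67 to 0.18). On set 1, H1-2, a linker histone, fell by 1.16 (SE 0.22, n = 5, 5 of 5 arrays, adjusted p = 0.033), and MSX1, HDLBP and REM1 stood at 0.58, 0.75 and 1.20 (adjusted p = 0.406 for each), and the 1 oligonucleotide of HDLBP that could be tested stood at 0.37. The 9 ribosomal protein genes of set 1 lay higher by camera (median 0.36, adjusted p = 0.00482, 0 passing singly and 0 adjusted over the list alone), while the list of set 2 lay lower. Of the 8 members tested on both sets, 6 had the same sign on both, with medians of 0.43 on set 1 and 0.14 on set 2, and RPL6 stood at -0.68 on set 1, so the directions of the lists differ mainly through other members. The 6 oxidative phosphorylation genes of set 1 lay lower (median -0.53, adjusted p = 0.00482), with 0 passing singly, or 3 that fell adjusted over the list alone. For both lists the adjusted p was 0.121 with an estimated correlation.

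In total 56 of 3340 genes changed on set 2 and 1 of 787 on set 1 under OHT at 24 h, and 539 and 62 had an unadjusted p under 0.05. The set 2 count was 1 without centring, 1 without a dye coefficient, 0 without the filter, 290 without the sparse arrays, 61 (24 higher and 37 lower) with the brightness trend removed, 199 (35 higher and 164 lower) with scaled arrays, 91 with the compared arrays alone, 89 with a dye coefficient per class, 87 with genes measured on all arrays and 570 (218 higher and 352 lower) with array weights, and it was 0 without replicate 2, 0 without replicate 3, 0 without replicate 4, 26 without replicate 5 and 28 without replicate 6. No array of this group on set 2 was sparse, so the 290 did not come from leaving out its own arrays. Without the sparse arrays of the other groups the 51 fallen genes kept their median of -0.913. Their median SE went from 0.208 to 0.19. The set 1 count was 31 with array weights, 3 with the compared arrays alone and 0 without replicates 2, 4, 5 or 6.

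**Figure D3:**
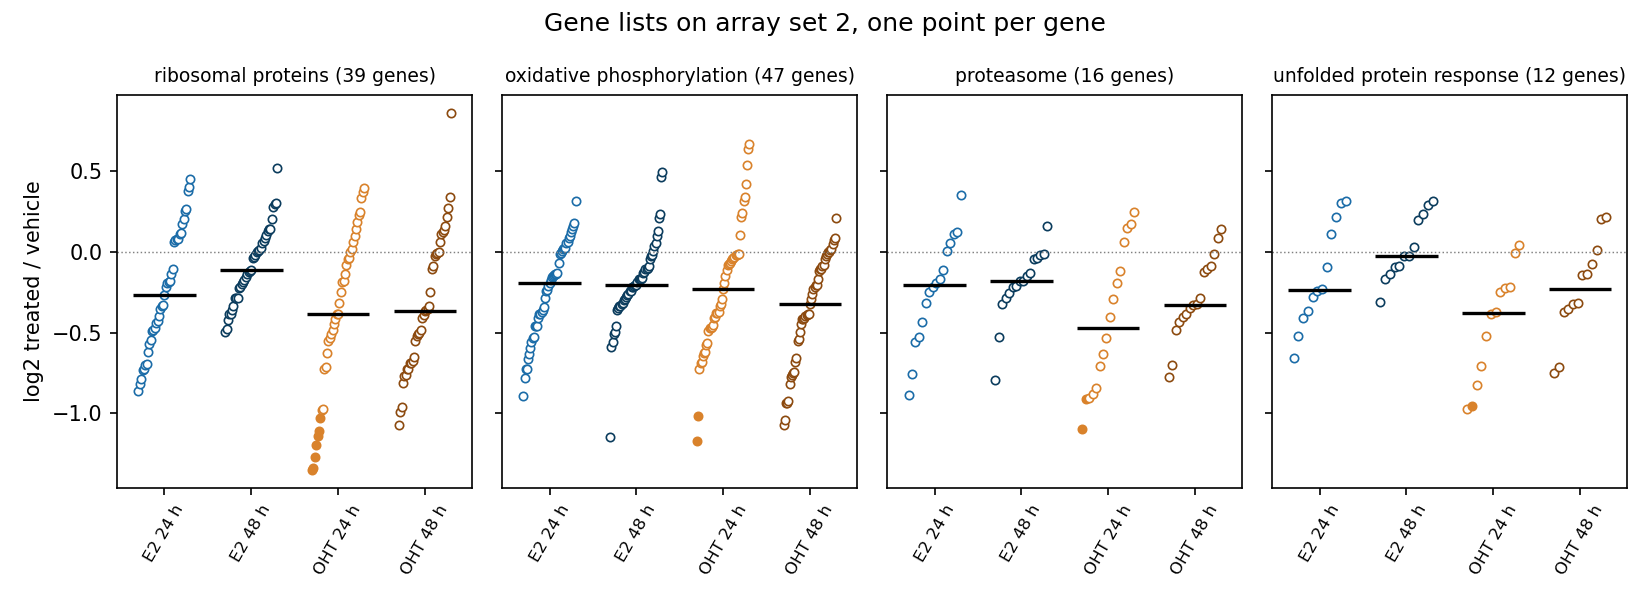
Log2 ratio to vehicle (vertical axis) of the set 2 members of 4 gene lists in the 4 groups of drug and time, with filled points for genes with an adjusted p under 0.05 and black lines for list medians. At 24 h of OHT 7 of 39 ribosomal protein genes and 2 of 16 proteasome genes fell.

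OHT at 48 h was compared with vehicle to find the later response to the antiestrogen. No single gene passed by limma, and 465 of 3340 genes on set 2 and 70 of 787 on set 1 had an unadjusted p under 0.05. The 47 oxidative phosphorylation genes of set 2 lay lower as a group by camera (median -0.32, adjusted p = 8.07e-08), and 0 fell singly, or 13 adjusted over the list alone. With an estimated correlation the adjusted p was 0.264. The median of this list was -0.20 with the brightness trend removed (adjusted p = 0.00498), -0.22 without the sparse arrays (adjusted p = 0.00406) and -0.21 without the filter, and the effects of OHT at 48 h over all genes had a Spearman rho of -0.291 with the brightness stand-in. Members with small p were ATP5MG, a subunit of ATP synthase, at -0.93 (SE 0.22, adjusted p = 0.155), COX7A2, a subunit of cytochrome c oxidase, at -1.07 and ATP5IF1, the inhibitor of ATP synthase, at -0.78 (adjusted p = 0.163 for each). The 39 ribosomal protein genes lay lower (median -0.37, adjusted p = 0.000162), and 7 fell adjusted over the list alone. With an estimated correlation their adjusted p was 0.635. RPS28 stood at -0.76 and RPL37 at -0.69. The 16 proteasome genes lay lower (median -0.33, adjusted p = 0.00833, 0 adjusted over the list alone), with an adjusted p of 0.543 with an estimated correlation.

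CKB stood at 0.77 after OHT at 48 h (SE 0.18, 6 of 6 arrays, adjusted p = 0.155). ZNF337, a zinc finger protein, stood at 1.79 (adjusted p = 0.132), and PPP1R9A, a regulatory subunit of protein phosphatase 1, at 1.14 and S100A13, a calcium-binding protein, at -0.96 (adjusted p = 0.148 for each). EIF3M, a translation initiation factor subunit, stood at -1.64 (adjusted p = 0.155). PGR stood at 1.08 (interval 0.26 to 1.90, 4 of 4 arrays, adjusted p = 0.231), with 1 array at 2.76 and the others between 0.31 and 0.68. GREB1 stood at 0.20 (interval -0.22 to 0.62), with 0.58 (unadjusted p = 0.0209) and -0.02 for its 2 oligonucleotides, and ALPP at -0.40 (interval -0.83 to 0.02). On set 1, ADCY7, an adenylyl cyclase, stood at 1.20, and RSAD2, an interferon-induced antiviral protein, at -1.11. ZCCHC10, GPATCH8, PIK3R3 and IDS stood at 0.67, 0.73, -0.79 and -1.29. These 6 genes had an adjusted p of 0.483. The 2 oligonucleotides of PIK3R3 pointed opposite ways, at -1.38 and 0.17, and the 2 of IDS that could be tested stood at -0.91 and -0.28.

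Without the sparse arrays, 3 of the 6 in this group on set 2, the ribosomal list (median -0.18, adjusted p = 0.609) and the proteasome list (median -0.23, adjusted p = 0.133) no longer passed, and with the brightness trend removed neither passed (adjusted p = 0.0754 for each), at medians of -0.27 and -0.18. The set 2 count at 48 h of OHT was 143 in 1 matching of averaged pairs, 5 without replicate 1, 28 without replicate 2, 1 without replicate 3, 21 with genes measured on all arrays and 3 with the trend removed, and the set 1 count was 8 without the filter and 1 without replicate 2.

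E2 and OHT, a steroid estrogen and a nonsteroidal antiestrogen, were compared at matched times to find genes on which they differ. Their doses differed, 10 nM and 1000 nM. PECR stood 0.70 higher after E2 than after OHT at 24 h (interval 0.20 to 1.20, adjusted p = 0.999) and 0.72 higher at 48 h (interval 0.22 to 1.22, adjusted p = 0.757). GREB1 stood 0.63 higher at 24 h (interval 0.11 to 1.14, adjusted p = 0.999), PADI2 1.38 higher at 48 h (interval 0.57 to 2.20, adjusted p = 0.757) and GDPD5 1.66 higher at 24 h (interval 0.75 to 2.57, adjusted p = 1). For CKB the difference at 24 h was 0.12 (interval -0.39 to 0.63), which does not show that the drugs act alike on it. The values of CKB at 24 h and PECR at 48 h lay outside the naming rule and were chosen after they were seen. At 24 h GJB6, a gap junction protein, stood 0.81 higher after E2, while GGH, NUCB2 and TPP1 differed by -0.87, -1.32 and -0.76. At 48 h UXS1 and GATD3 differed by 0.71 and 1.02, and ZNF337, APBB3 and SEC24D by -1.99, -1.18 and -1.52. On set 1, TMEM37, PLPP3, AMOT, BIN2 and PBXIP1 differed at 24 h by 0.97, 0.65, -0.67, -0.90 and -0.47. At 48 h MECR, PAPSS1, GPSM2, AJUBA and ZNF771 differed by 3.37, 1.47, -1.80, -1.02 and -1.06, and GDPD5 by 1.63.

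The 12 genes of the unfolded protein response on set 2 lay higher after E2 than after OHT at 24 h by camera (median 0.32, adjusted p = 0.00685, 0 passing singly and 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.585. The 9 ribosomal protein genes of set 1 lay lower after E2 than after OHT at 24 h (median -0.17, adjusted p = 0.0347, 0 adjusted over the list alone), with an adjusted p of 0.414 with an estimated correlation. No gene differed by limma at either time on either set. The genes with an unadjusted p under 0.05 were 42 of 3340 at 24 h and 193 at 48 h on set 2, where chance would give 167, and 9 of 787 and 53 on set 1, where chance would give 39.35. The unfolded protein response no longer passed without the sparse arrays (median 0.29, adjusted p = 0.174), with the brightness trend removed (median 0.20, adjusted p = 0.0573) or with scaled arrays (median 0.27, adjusted p = 0.106), and the ribosomal list of set 1 not with the trend removed (adjusted p = 0.222). With E2 and OHT arrays of neighbouring slides as pairs, an alternative added after the data were seen, 1 gene passed at 48 h on set 2, MMP17 (2.94 higher after E2, 4 of 4 pairs, adjusted p = 0.0238, against 2.56 and 0.757 without pairs), and 367 of 3313 genes had an unadjusted p under 0.05 at 24 h; the count of passing genes was also 1 on set 2 at 24 h without replicate 6 of E2, and 27 at 48 h in 1 matching of averaged pairs.

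The 48 h and 24 h effects of each drug were compared to find genes whose response grew or faded. Under E2, PADI2 stood 1.38 higher at 48 h than at 24 h (interval 0.65 to 2.10, adjusted p = 0.996). SNX5, a sorting nexin, stood 2-fold higher. TTC19, a complex III assembly factor, differed by 0.92, and ZNF444, TRMU and PGAM1 by -1.12, -1.27 and -0.85. Under OHT, ZNF337 differed by 1.89, SFMBT1 by 1.38, VPS36 by 1.34, CEP72 by -1.06, ZNF213 by -0.59 and ZNF264 by -1.14 (adjusted p = 0.892 for each). On set 1, ELP4, CD244, LDAF1, MAGEE1, CHPF and TAOK2 differed under E2 by 1.35, 1.64, 0.95, -1.37, -0.89 and -1.06. Under OHT, CIRSR, CGB3, KLHL42, PIK3R3, RSAD2 and REM1 differed by 1.34, 1.88, 0.76, -0.98, -1.52 and -1.93. The 6 oxidative phosphorylation genes of set 1 lay higher at 48 h than at 24 h under E2 (camera median 0.44, adjusted p = 0.0028), with an adjusted p of 0.157 with an estimated correlation. They also lay higher under OHT (median 0.43, adjusted p = 0.0174), with an adjusted p of 0.298 with an estimated correlation. The 47 such genes of set 2 lay lower at 48 h under OHT (median -0.14, adjusted p = 0.00822), with an adjusted p of 0.92 with an estimated correlation. In these 3 tests 0 members passed over all genes and 0 adjusted over the list alone. No gene differed by limma, and the genes with an unadjusted p under 0.05 were 105 for E2 and 151 for OHT on set 2, and 44 and 42 on set 1. On set 2 the oxidative phosphorylation call ended without the sparse arrays (adjusted p = 0.586), with the trend removed (adjusted p = 0.151) and with scaled arrays (adjusted p = 0.55), and on set 1 the call under OHT ended without the sparse arrays (adjusted p = 0.0543).

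The other lists did not pass against vehicle on set 2 in the main fit. More lists passed in some alternatives, 7 against 3 for OHT at 24 h without the filter and 3 against 1 for E2 at 24 h with scaled arrays. For OHT at 48 h 7 passed against 3 in 1 matching of averaged pairs. With an estimated correlation 0 passed in each of these comparisons. After OHT at 24 h the 40 cell cycle genes had a median of -0.19 (adjusted p = 0.097), and RRM1, the large subunit of ribonucleotide reductase, was the 1 member that fell (by 0.80, adjusted p = 0.0309), or 2 adjusted over the list alone. The 10 heat shock proteins had a median of -0.42 (adjusted p = 0.0796), with 0 passing, or 5 adjusted over the list alone, and HSPA4 at -0.80. The 6 interferon response genes had a median of 0.15 (adjusted p = 0.0859). The adjusted p at 24 h of OHT was 0.739 for estrogen receptor targets, 0.739 for endometrial hormone genes, 0.739 for cholesterol synthesis, 0.613 for fatty acid synthesis, 0.815 for growth factors and the IGF system and 0.391 for immediate early genes. It was 0.253 for nuclear receptors and coregulators, 0.815 for the BCL2 family and caspases, 0.272 for xenobiotic and oxidative defence, 0.815 for extracellular matrix and adhesion, 0.409 for WNT signalling, 0.258 for epithelial keratins and 0.272 for housekeeping genes. Stromal markers, 2 genes with a median of 0.03 after OHT at 24 h, and blood and endothelial markers, 1 gene at -0.35, were too few to test.

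Across genes, which are not independent replicates, the log2 ratios of E2 and OHT at 24 h on set 2 had a Pearson r of 0.562, those of OHT at 24 and 48 h 0.435, those of E2 at 24 and 48 h 0.282 and those of E2 and OHT at 48 h 0.194. On set 1 these were 0.48, 0.115, 0.197 and -0.01. The sets shared 63 tested genes, over which r between sets was 0.547 for E2 at 24 h, 0.534 for OHT at 24 h, -0.000472 for E2 at 48 h and -0.08 for OHT at 48 h. The sign was the same in 42 of 63 genes (66.7%, Spearman rho 0.516) for E2 at 24 h and in 32 of 63 (50.8%, Spearman rho 0.39) for OHT at 24 h. Of the genes that fell on set 2 at 24 h of OHT, 3 were also tested on set 1 and stood lower there, LDHB, a lactate dehydrogenase subunit (-1.02 and -0.50), ELOB, an elongin subunit (-0.94 and -0.66), and RPL6 (-1.34 and -0.68). LDHB and ELOB lay outside the naming rule and were chosen after their values were seen.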

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

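In this part, the tests of the ribosomal list, of a dye coefficient for each class of arrays, of neighbouring slides and of shared vehicle RNA or hybridisation day were chosen after the results were seen, and the fits without sparse arrays, with a dye coefficient per class, with neighbouring slides as pairs and with the brightness trend removed were added after the data were seen.

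The tests for an array far from the others covered named genes in a group and the number of spots with a value in each group. In 5 of 52 such tests 1 array lay far from the others, where chance would give 2.6. All 5 were of named genes. SELENOT lay at -3.35 on 1 array of E2 at 24 h, with the others between -1.31 and -0.42. RPS4X lay at -3.12 on 1 array of OHT at 24 h, with the others between -1.47 and -0.68. PGR lay at -1.64 on 1 array of E2 at 48 h, with the others between 0.80 and 1.13, and at 2.76 on 1 array of OHT at 48 h, with the others between 0.31 and 0.68. GREB1 lay at 0.73 on 1 array of OHT at 48 h, with the others between -0.01 and 0.08.

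Groups differed in 5 direct tests of 3 gene lists, none of which passed with an estimated correlation. On set 2 the unfolded protein response genes lay higher after E2 than after OHT at 24 h (camera adjusted p = 0.00685, adjusted p = 0.585 with an estimated correlation). On set 2 the oxidative phosphorylation genes lay lower at 48 h than at 24 h of OHT (adjusted p = 0.00822, adjusted p = 0.92 with an estimated correlation). On set 1 they lay higher at 48 h than at 24 h of E2 (adjusted p = 0.0028, adjusted p = 0.157 with an estimated correlation) and of OHT (adjusted p = 0.0174, adjusted p = 0.298 with an estimated correlation). The ribosomal protein genes of set 1 lay lower after E2 than after OHT at 24 h (adjusted p = 0.0347, adjusted p = 0.414 with an estimated correlation).

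Spots with no gene name were tested singly and without the alternatives, so repeated spots of 1 oligonucleotide may count more than once. Of 510 tested on set 2, 10 fell after OHT at 24 h, against 56 of 3340 genes changed in that comparison. Of these spots 97 had an unadjusted p under 0.05, where chance would give 25.5, and 1 fell after E2 at 48 h. Of 202 tested on set 1, 2 rose after OHT at 48 h.

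The first pattern weighed was the fall of 51 genes after OHT at 24 h on set 2, with a median log2 ratio of -0.913, among genes whose brightness stand-in had a median of 78.6% against 42.9% for all genes. After removal of the brightness trend their median was -0.738 (quartiles -0.875 and -0.617) and 34 of the 51 still passed. This argues against the trend, as the stand-in measures it, as the whole cause of their low values, although they were chosen as low on these arrays. The calls went from 5 higher and 51 lower to 24 higher and 37 lower, so much of the imbalance was not kept. Without centring the median was -0.971 and 1 gene passed, for a cause not tested, with a median SE of 0.241 against 0.208. Centring moved the median of all genes only between -0.13 and -0.06. That is too little to make or undo a fall of this size, so this test could not have turned out otherwise. For the ribosomal list, a fall by OHT and a brightness trend cannot be told apart, since its median went from -0.385 to -0.162, between the bounds of -0.1 and -0.3 set for the test. Giving the treated dye to other sets of 3 arrays called at most 0 genes against 56, but 10 ways are too few for a share under 0.05. An action of OHT may remain for the other genes, untested apart from these, and with 0 calls without replicate 2, 3 or 4.

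The second pattern was that 42 genes had an unadjusted p under 0.05 between E2 and OHT at 24 h on set 2, where chance would give 167. Noise shared by arrays on neighbouring slides may explain the low count, since 367 genes had such a p with E2 and OHT arrays of neighbouring slides as pairs, and the residuals of 5 such pairs correlated with a median of 0.336, against -0.0531 for 13 other pairs of 1 orientation. What neighbours share, vehicle RNA, a culture or a hybridisation day, is not stated; residuals of E2 and OHT arrays at 24 h correlated above those of different times by 0.153 in the median, an excess found in arrays of the same class of spot numbers (0.289 against -0.0427 between times) and not in others (-0.144 against -0.141). On set 2 noise of the class and of the neighbours cannot be told apart. There a dye coefficient for each class gave 68 genes, while pairs of 1 class on other slides, only 3, had a median of 0.0289. On set 1 at 24 h, 10 such pairs had a median of -0.0018 against 0.245 for 6 neighbouring pairs. Neighbours there correlated above other pairs of 1 class, and 9 of 787 genes became 50 of 779 with pairs. A coefficient per class gave 11 of 526 genes there. It cannot decide, since all 6 arrays of E2 and 5 of the 6 of OHT were of 1 class. Shared vehicle RNA would make effects of both drugs resemble each other, so the r of 0.562 between them across genes is not evidence of a like action.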

How the results depend on the processing

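The dye coefficient per class of arrays, the fit without sparse arrays, the removal of the brightness trend and the pairs of neighbouring slides were chosen after seeing the data. The list calls were summed over the 8 comparisons of a set, a choice also made after a first look, and were 6 on set 1 and 11 on set 2. Where no cause is named, the cause was not tested. Counts, lists and agreement between sets kept within 1.5 times of their value, or within their spread, in 298 comparisons with an alternative and left it in 104. A count of 0 that stayed 0 was taken as kept. The count was 0 in the main fit for OHT at 48 h and for every comparison between drugs or between times, on both sets. The 298 therefore say little about the stability of called genes. Named genes kept their direction and side of the threshold in 1134, lost the call in 146, gained one in 26 and took the opposite sign in 5. The 1134 include genes that were not called and stayed so, while the 146 losses were all of called genes. Among called genes the call was kept in 3 and lost in 29 in the weakest matching of averaged pairs. It was kept in 9 and lost in 23 with the weakest choice of 1 array left out, and kept in 31 and lost in 1 with array weights. Most stable were ESPN and PECR at 48 h of E2, kept in 11 of 12 alternatives each (adjusted p up to 0.0895), and CABLES1 at 24 h, kept in 9 of 10. Calls lost in most alternatives were SLC7A5 at 48 h of E2 (8 of 11, adjusted p up to 0.801), KAZN (8 of 12) and CKB (7 of 12) at 24 h, NDUFA11 at 48 h (7 of 12), and SELENOT at 24 h and MMP17 at 48 h (6 of 11 each). With a dye coefficient per class (adjusted p = 0.0228) and without sparse arrays (adjusted p = 0.0433) a call was gained by PGR, E2 at 48 h, array set 2, at 0.87 and 0.88. The sparse signal of set 1, where 73.7% of spot values were missing, limits what it can show.

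Array weights gave 16, 18 and 31 genes on set 1 for E2 at 24 h, E2 at 48 h and OHT at 24 h, 10 for E2 at 48 h against 24 h and 2 for E2 against OHT at 48 h. On set 2 they gave 457, 19 and 570 for E2 at 24 h, E2 at 48 h and OHT at 24 h. Scaled arrays gave 1 for E2 at 24 h and 0 for E2 at 48 h on set 1, and on set 2 43 for E2 at 24 h (18 higher and 25 lower against 6 and 2) and 199 for OHT at 24 h (35 and 164 against 5 and 51), and raised r between sets for E2 at 48 h against 24 h from 0.295 to 0.519. No centring gave 1 for E2 at 48 h on set 1, and on set 2 0 for E2 at 24 h and 1 for OHT at 24 h. It moved the median log2 ratio of all genes from -0.06 to -0.19 (E2 at 24 h, set 2), from 0.01 to 0.17 (E2 at 48 h, set 2) and from 0.03 to -0.12 (OHT at 24 h, set 1), so changes are relative to the array median. No dye coefficient gave 1 for E2 at 48 h and 0 for OHT at 24 h on set 1, and 5 for E2 at 24 h and 1 for OHT at 24 h on set 2.

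No filter gave 8 for E2 at 48 h, 0 for OHT at 24 h, 8 for OHT at 48 h, 1 and 5 for 48 h against 24 h of E2 and OHT and 3 for E2 against OHT at 48 h on set 1, and 5 for E2 at 24 h, 0 for OHT at 24 h and 1 for OHT at 48 h on set 2. Genes measured on all arrays, 75 and 689, gave 0 for E2 at 24 h and 1 for E2 at 48 h on set 1, 87 for OHT at 24 h and 21 for OHT at 48 h on set 2, and 2 and 4 list calls, with fewer genes tested. The compared arrays alone gave 0 for E2 at 48 h and 3 for OHT at 24 h on set 1, and 0 for E2 at 24 h, 1 for E2 at 48 h and 91 for OHT at 24 h on set 2, with fewer arrays behind each variance.

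The dye coefficient per class gave 0 for E2 at 24 h and 1 for E2 at 48 h on set 1, where 526 genes could be tested, and 5, 22 and 89 for E2 at 24 h, E2 at 48 h and OHT at 24 h on set 2. Without sparse arrays the counts were 1 for E2 at 48 h on set 1, and 15 for E2 at 24 h and 290 for OHT at 24 h on set 2. The last of these groups held no sparse array, so its own arrays were unchanged. For E2 at 48 h on set 2, 7 genes passed, 2 of them among the 8. With the brightness trend removed they were 4, 5 and 2 for E2 at 24 h, E2 at 48 h and OHT at 24 h on set 1, 18 for E2 at 48 h and 3 for OHT at 48 h on set 2, and 6 list calls on set 2. For OHT at 24 h on set 2 this gave 61 genes, 24 higher and 37 lower.

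Averaged pairs gave at the lowest of the 6 matchings 0, 0 and 0 for E2 at 24 h, E2 at 48 h and OHT at 24 h on set 1, and 0, 4 and 0 on set 2, with 1 list call on set 1. At the highest they gave on set 1 5 for E2 at 24 h, 0 for OHT at 24 h, 8 for OHT at 48 h, 3 and 3 for 48 h against 24 h of E2 and OHT and 8 for E2 against OHT at 48 h. On set 2 the highest were 3 for E2 at 24 h, 39 for E2 at 48 h, 143 for OHT at 48 h, 8 and 13 for 48 h against 24 h of E2 and OHT and 27 for E2 against OHT at 48 h, with 22 list calls. Pairs leave 3 samples per group. On set 1, 1 of the 6 matchings follows the slide numbers, and its counts were not read apart. E2 and OHT arrays of neighbouring slides, with 1 pair of the 6 at 24 h on set 2 not neighbouring, gave as pairs 0 genes at 24 h on both sets, 0 at 48 h on set 1 and 1 at 48 h on set 2, MMP17. The labels do not state this pairing. As a hint from the data, the residuals of neighbours correlated with medians of 0.245 and 0.263 at 24 and 48 h on set 1. On set 2 these were 0.336 and 0.00211. For other pairs the medians were -0.0166 and -0.0949 on set 1 and -0.0531 and -0.119 on set 2. The 2 list calls between drugs at 24 h were kept with these pairs (adjusted p = 0.0393 on set 1 and 0.00899 on set 2). The estimated correlation gave 0 list calls on both sets. Fry gave 0 and 5, and the 5 were 3 for OHT at 24 h and 2 for OHT at 48 h. It needs complete values, so it ran on genes measured on all arrays, with 1 list on set 1 and 8 on set 2.

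List by list, genes measured on all arrays alone ended the set 2 calls of oxidative phosphorylation at 24 h of E2 (adjusted p = 0.128), of the 3 lists at 24 h of OHT (adjusted p from 0.154 to 0.238), of ribosomal proteins (0.117) and the proteasome (0.17) at 48 h of OHT and of the proteasome at 48 h of E2 (0.198). No filter ended the proteasome at 48 h of OHT (0.212), and the dye coefficient per class also did (0.0592). The unfolded protein response between drugs also ended without the filter (0.0887) and with array weights (0.169), as did oxidative phosphorylation between times of OHT (0.387 and 0.484). On set 1, oxidative phosphorylation at 24 h of E2 ended in 7 alternatives (0.0533 to 0.398) and the ribosomal difference in 7 (0.0568 to 0.222), and each also in at least 1 matching of averaged pairs, and both oxidative phosphorylation differences between times ended without the filter (0.106 and 0.155). For oxidative phosphorylation between times of OHT on set 2 the list median went from -0.14 to 0.02 without sparse arrays and to -0.01 with scaled arrays, so that fall was not kept there.

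Leaving out 1 array gave 1 to 2 genes for E2 at 24 h, 0 to 3 for E2 at 48 h, 0 to 1 for OHT at 24 h and 0 to 1 for OHT at 48 h on set 1. On set 2 it gave 3 to 7 for E2 at 24 h, 5 to 8 for E2 at 48 h, 0 to 48 for OHT at 24 h, 0 to 28 for OHT at 48 h and 0 to 1 for E2 against OHT at 24 h, and 0 to 0 in the other comparisons of both sets. The arrays behind these ranges were, for OHT at 24 h on set 2, replicates 2, 3 and 4 with 0 genes each, and for OHT at 48 h on set 2, replicate 2 with 28.

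The 5 values of the opposite sign belonged to comparisons in which the gene was not called in the main fit. Without sparse arrays the log2 ratio was 0.01219 for ALPP, E2 at 48 h, array set 2, and 0.000688 for ALPP, OHT at 48 h, array set 2. With array weights it was -0.01451 for GREB1, OHT at 24 h, array set 2, and 0.02727 for PGR, OHT at 24 h, array set 2. With averaged pairs it was at its weakest -0.00425 for GREB1, OHT at 48 h, array set 2.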

Other observations

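In this part, both tests of the genes raised by E2 and the exchange of drugs within pairs of neighbouring slides were chosen after the results were seen.

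The genes raised by E2 at 24 h, KCNJ5, PECR, ESPN, SLC7A5, CKB, KAZN, GDPD5 and CABLES1, mostly stood between vehicle and E2 under OHT. On the separate 48 h arrays all 8 stood higher than vehicle under E2, from 0.90 to 1.89, with a median of 1.10, which argues against a chance selection of high values at 24 h. Their median under OHT was 0.504 at 24 h and 0.476 at 48 h, and E2 stood above OHT in 8 of 8 at 48 h, by 0.31 to 1.63 with a median of 0.562. The members differed, since GDPD5 stood near 0 under OHT (0.05 at 24 h and 0.25 at 48 h) and CKB almost as high under OHT as under E2 at 24 h (0.73 and 0.85). As a hypothesis, OHT may act on most of these genes in the direction of E2 but less strongly. No single gene passed the test of that difference, the doses were 10 and 1000 nM, and vehicle RNA shared by the arrays of both drugs was not excluded.

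DUSP6 and EGR1, growth factor-induced genes of the immediate early list, stood at 0.94 (adjusted p = 0.0786) and 0.63 (adjusted p = 0.571) after E2 at 48 h, and EGR1 at 0.75 (adjusted p = 0.195) after OHT at 48 h. CCNB1, the mitotic cyclin, stood at -0.90 (adjusted p = 0.11) after E2 and -0.76 (adjusted p = 0.053) after OHT at 24 h. HSPA8, a chaperone of the cytosol, stood at -0.93 (adjusted p = 0.115) at 24 h and -1.22 (adjusted p = 0.163) at 48 h of OHT. SOD1, a superoxide dismutase, stood at -0.88 (adjusted p = 0.118) and -0.89 (adjusted p = 0.195) at these times. None of these genes passed.

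Other groupings of the arrays were counted. For each drug against vehicle, the 6 arrays allow 10 ways of giving 3 of them the treated dye, too few for a share under 0.05. The labels gave 2 genes for E2 at 24 h, 2 for E2 at 48 h and 1 for OHT at 24 h on set 1, where the highest other way gave 0, 1 and 0, and only 1 of 10 ways, the real one, gave as many. On set 2 they gave 8, 8 and 56, and the highest other way 1, 1 and 0, again with 1 of 10 ways as large. For OHT at 48 h the labels gave 0 genes on both sets, which all 10 ways reached, and the highest other way gave 1 on each.

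For the comparisons of E2 with OHT and of 48 h with 24 h, 100 splits of the 12 arrays into 6 and 6 were counted by genes at an unadjusted p under 0.05, and in none was chance excluded by them. These splits take the arrays as independent, although E2 and OHT arrays of neighbouring slides deviated together at 24 h on both sets and at 48 h on set 1. In those comparisons they do not decide whether the drugs differ. At 48 h on set 2 the residuals of neighbours had a median correlation of 0.00211, against -0.119 for 12 other pairs. The excess was smaller there, and this limit is not excluded. On set 1, E2 against OHT gave 9 genes at 24 h (83 splits as large, highest other 104) and 53 at 48 h (52 splits, highest other 135). On set 1, 48 h against 24 h gave 44 under E2 (37 splits, highest other 113) and 42 under OHT (22 splits, highest other 95). On set 2, E2 against OHT gave 42 at 24 h (65 splits, highest other 374) and 193 at 48 h (76 splits, highest other 598). On set 2, 48 h against 24 h gave 105 under E2 (65 splits, highest other 367) and 151 under OHT (36 splits, highest other 377). Some splits gave several times the real count, and what sets the high ones was not tested. The medians of the other splits on set 2, in that order, were 63, 241, 131 and 130.

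With E2 and OHT arrays of neighbouring slides as pairs, the drugs were exchanged within pairs in all 32 ways. On set 2 at 24 h the labels gave 367 genes at an unadjusted p under 0.05, where chance would give 165.65, and the highest other way gave 298. So 1 of 32 ways was as large, the smallest share that this exchange can reach. With 4 such tests, chosen after the results were seen, and a pairing the labels do not state, this does not exclude chance. Nor was chance excluded on set 2 at 48 h (146 genes, 2 ways as large, highest other 170). The same held on set 1 at 24 h (50 genes, 4 ways, highest other 74) and at 48 h (50 genes, 3 ways, highest other 65).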
